A study of Mus musculus with 2 samples.

How the data were processed

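Total RNA of B-Gal positive and B-Gal negative cells from healing skin of TCF reporter mice, taken 1 week after wounding, was labelled with biotin and hybridised to Affymetrix Mouse Gene ST arrays, 1 array per group, per the labels. The series' design text adds that wound tissue was microdissected and homogenised, that RNA was extracted with a Qiagen kit, and that its quality was assessed on a Bioanalyzer. How cells were assigned to the B-Gal positive and B-Gal negative groups is not given in the sources used here. The number of mice behind each array is not given in them either. Homogenised tissue holds all its cells, so how the described extraction relates to separate cell groups is open. The platform annotation used here named no lacZ probe set, so the group labels were not checked against the reporter.

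The deposited table holds 1 value per probe set and array, used here as log2 expression values. Per the submitters' processing notes, the software was Partek, with no version or role. The summarization, background correction, normalization and log base are not given in the sources used here. A log2 scale was inferred from the values, which ran from 1.16 to 14.8, and folds depend on that reading. Array medians were 6.18 for B-Gal negative and 6.16 for B-Gal positive. The sorted values of both arrays differed by at most 0.594, so their distributions were close and not identical. No scaling was added in the comparison reported.

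Of 28853 probe sets, 21789 were paired with 1 gene by the platform annotation used here, 1621 with several genes, and 5443 were not listed in it. Symbols of single-gene probe sets were updated by gene ID with a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. That table matched 21698 of them, and 0 symbols differed. Probe sets with several genes or none listed were left out of the gene comparison. For the 999 genes with more than 1 probe set, out of 19938 genes, the probe set with the highest mean of both arrays was used.

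A floor was set at the 95th percentile of the values of 1194 olfactory and vomeronasal receptor genes, which skin cells are not known to use widely. It lay at 5.59 on the log2 scale, and genes with at least 1 array above it, receptor genes left out, were counted as expressed (13784 genes). The difference of a gene is the log2 value in B-Gal positive cells minus that in B-Gal negative cells, and genes differing at least 2-fold were counted by direction. Counts, medians and the choice of the 12 genes per direction used the deposited values, also where 1 array lay at or under the floor. The fold printed for such a gene was computed against the floor and is given as at least that size. No p-value was computed.

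Gene lists for cell types, pathways and wound processes, 36 in all, were written before the data were examined. A list's median difference over its expressed members was placed as a percentile among the medians of 10000 random lists of the same size, drawn with replacement from expressed genes in 20 bins of mean expression. A list is said to stand apart at or under percentile 2.5 or at or over 97.5. These percentiles describe the 2 arrays and are not evidence about other mice. Of the 960 list entries, 65 had no probe set naming the gene alone. The genes named in the text were set by rule before the data were examined. They were the 12 expressed genes with the largest difference in each direction, leaving out predicted, clone-named, small RNA and antigen receptor segment genes, up to 4 members of each list with the largest absolute difference, and 14 fixed genes. Tcf7 and Gapdh were among the fixed genes and had no probe set naming them alone. Genes named outside this rule are said to be so.

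The alternatives were centring of array medians, a loess fit of the difference on the mean (span 0.4, 3 iterations), quantile normalization, and an offset of 32 added on the linear scale. Others were no filter on low values, a floor at the 99th percentile of receptor genes, a filter at the median of all genes, the mean over a gene's probe sets, thresholds of 1.5-fold and 4-fold, list means, lists without their largest member, and random lists without matching. Alternatives added after the data were seen raised values under the floor to the floor, or left out members that another list also holds or that the macrophage and pan-leukocyte lists hold.

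The procedure was tested on simulated data built on the 13784 expressed genes, with the spread of the receptor genes as noise. Of 100 genes shifted by 1.5 on the log2 scale, 93% were called at least 2-fold different in the right direction, and of 100 shifted by 3, 100%. Among 13584 genes left unshifted, 0.707% were called. Of 200 unshifted lists of 20 genes, 6% stood apart, and of 200 shifted by 0.5, 99% did. The noise of each gene was drawn independently around 0. The receptor genes themselves had a median difference of 0.28, and 2.68% of them differed at least 2-fold. Genes of a list may also vary together, which was not simulated. These rates therefore describe the simulation and not the error of the 2 arrays. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.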

Results

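Gene expression was measured in cells from healing mouse skin, 1 week after wounding. The mice were labelled as TCF reporter mice, read here as carrying a transgene that marks cells in which TCF transcription factors, the nuclear partners of beta-catenin in Wnt signalling, are active. The samples were labelled B-Gal positive and B-Gal negative, read here as the presence or absence of beta-galactosidase. How the cells were separated is not given in the sources used here, and the labels were not checked against the reporter. Each group had 1 array and no replicates, so no difference has an error or a test, and this number of arrays limits the precision. Log2 probe set values correlated at r = 0.917 across the 28853 probe sets and at 0.758 across the 13784 expressed genes, correlations across genes that are not independent replicates.

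The comparison asked which genes differed in expression between B-Gal positive and B-Gal negative wound cells. Macrophage genes were higher in the B-Gal positive array. Cd163, a scavenger receptor for haemoglobin and haptoglobin complexes, was at least 30.9-fold higher, and Mrc1, the macrophage mannose receptor, was 48.5-fold higher. Fibroblast and extracellular matrix genes were lower, among them Tnc, the tenascin C gene, which was 24.9-fold lower, and Pdgfra, a growth factor receptor gene of fibroblasts, which differed by -4.32 on the log2 scale. Mast cell, mural cell, endothelial and mitosis genes were also lower. The median difference of the TCF and beta-catenin target genes was -0.58 on the log2 scale, on the lower side in the cells labelled B-Gal positive.

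Among expressed genes, 1368 were at least 2-fold higher in B-Gal positive cells and 1753 were at least 2-fold lower, together 22.6% of those genes. Of the genes that differed this much, 43.8% were higher. With values under the floor raised to it, 1316 genes were higher and 1600 lower by this threshold. Differences of at least 16-fold were found for 32 genes on the higher side and 75 on the lower side. Raising values to the floor took 1 gene each out of the 2-fold counts of 7 lists: Wnt components, neutrophil, mast cell, skeletal muscle, mitosis, wound macrophage activation and matrix protease genes. By comparison, 32 of the 1194 olfactory and vomeronasal receptor genes (2.68%) differed at least 2-fold. The median difference was 0.14 over all probe sets, 0.06 over expressed genes and 0.28 over the receptor genes. Of the 36 gene lists, 9 stood apart on the higher side of random lists matched on expression and 15 on the lower side. The cutoffs would give 1.8 such lists if lists and their genes were independent. They are not, since lists share members and genes of a cell type may vary together, so 1.8 is no measure of chance here.

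**Figure D1:**
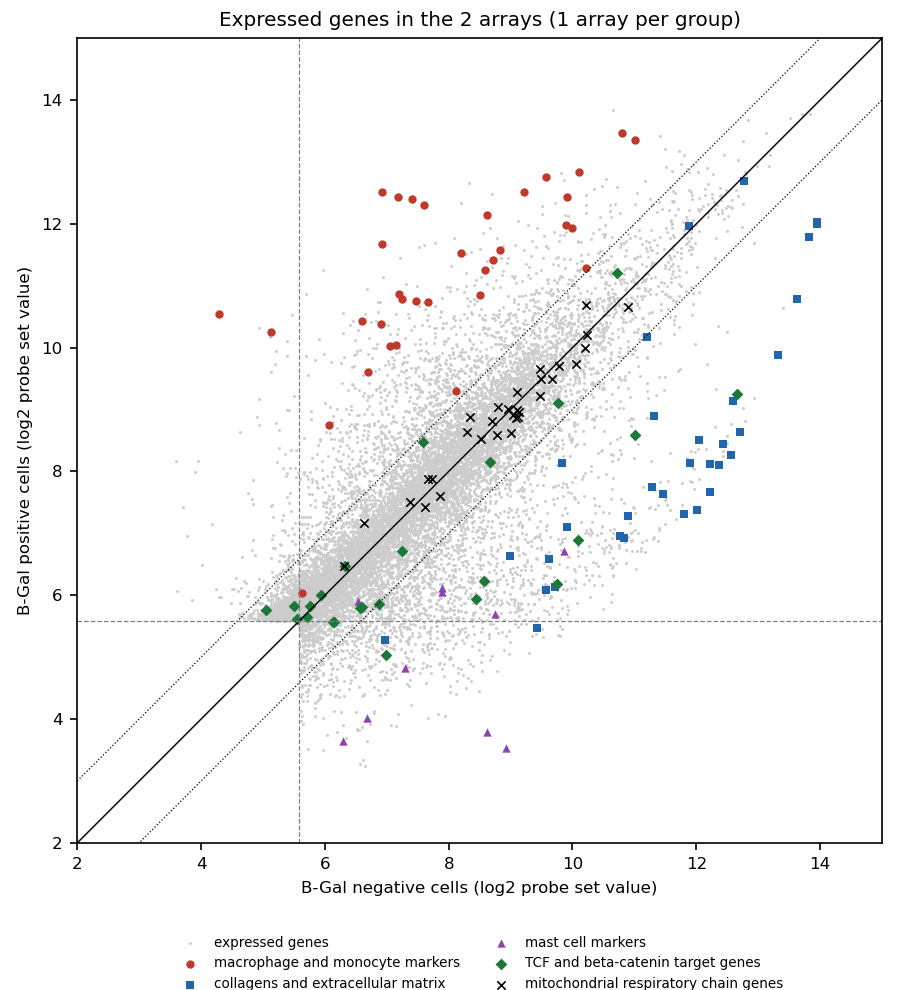
Log2 probe set values of the 13784 expressed genes in B-Gal negative cells (horizontal axis) and B-Gal positive cells (vertical axis), 1 array each, with members of 5 gene lists marked; the solid line marks equal values, dotted lines a 2-fold difference and dashed lines the floor of 5.59. Macrophage genes lie above the diagonal (median difference 3.03), collagen and matrix genes below it (-3.54), and respiratory chain genes along it (-0.03).

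All 34 expressed macrophage and monocyte markers had higher values in B-Gal positive cells, 33 of them by at least 2-fold. Their median difference was 3.03 on the log2 scale (percentile 100). C1qc and C1qa, which encode chains of the complement component C1q, were 38.1-fold and 31.9-fold higher. Ms4a7, a membrane protein gene of macrophages, was at least 25.5-fold higher, and Adgre1, which encodes a surface antigen of mouse macrophages, was 26.9-fold higher. Other genes with large differences were Cbr2, a carbonyl reductase (39.1-fold), Fcrls, an Fc receptor-like gene (at least 24.1-fold), Hpgds, a prostaglandin D synthase (at least 30.6-fold), and Tlr8, an endosomal receptor for RNA (at least 20.5-fold). The pan-leukocyte list had a median of 2.18 (percentile 100), with 23 of its 25 expressed members at least 2-fold higher and 0 lower. Among them were Cd48 (14.8-fold), the actin regulator Nckap1l (9.83-fold) and Dock2, an activator of Rac in leukocytes (8.80-fold). Ptprc, which encodes CD45, was 3.79-fold higher.

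Wound macrophage activation genes had a median of 1.95 (percentile 100), and 16 of 21 expressed members were at least 2-fold higher and 1 lower. Folr2, a folate receptor of macrophages, was 35.7-fold higher, the coagulation factor gene F13a1 20.3-fold, and the scavenger receptor gene Stab1 16.7-fold. Retnla, a gene of alternatively activated macrophages, was at least 8.24-fold higher. Lysosome genes had a median of 1.30 (percentile 100), with 22 of 34 at least 2-fold higher and 0 lower. Atp6v0d2, a proton pump subunit, was at least 26.5-fold higher, and the cathepsin genes Ctss and Ctsc were 5.08-fold and 4.58-fold higher. Glb1, the mouse's own lysosomal beta-galactosidase, was 1.25-fold higher.

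Interferon response genes were at least 2-fold higher for 14 of 24 members and lower for 0, with a median of 1.14 (percentile 100). Oasl1 (5.36-fold), Ifih1, a cytosolic sensor of double-stranded RNA (5.22-fold), and Rsad2 (5.21-fold) had the largest differences of this list. Dendritic cell and MHC class II genes had a median of 1.09 (percentile 100), with 7 of 14 at least 2-fold higher and 0 lower. The co-stimulatory ligand gene Cd86 was 9.15-fold higher, and Cd74, the invariant chain of MHC class II, 3.07-fold higher. The integrin gene Itgax, also in this list, was 4.75-fold higher. Of the 14 members, 10 had higher values and 4 had lower values in B-Gal positive cells. The 4 lower ones were the dendritic cell genes Ccr7, Zbtb46, Flt3 and Xcr1, named after their values were seen. They differed by -0.18, -0.21, -0.24 and -0.47. Inflammatory cytokine and chemokine genes went both ways around a median of 0.74 (percentile 99.9), 12 of 28 at least 2-fold higher and 5 lower. Il10, an anti-inflammatory cytokine, was 19.2-fold higher and the chemokine gene Ccl12 at least 9.76-fold higher. The neutrophil-attracting chemokine gene Cxcl5 was 20.9-fold lower and the alarmin gene Il33 15.4-fold lower.

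Collagen and extracellular matrix genes had the lowest median of the 36 lists, -3.54 on the log2 scale (percentile 0). Of 33 expressed members, 31 were at least 2-fold lower and 0 higher. The fibril-associated collagen gene Col12a1 was 23.3-fold lower, the collagen cross-linking enzyme gene Lox 22.4-fold lower and Thbs2, a matricellular protein gene, 19.6-fold lower. Fibroblast markers had a median of -3.31 (percentile 0), with 22 of 23 at least 2-fold lower and 0 higher. These included the proteoglycan gene Lum (18.1-fold), Dpt, which encodes dermatopontin (19.4-fold), and the fibulin gene Fbln2 (18.0-fold). Further genes with large differences on this side were Plod2, a lysyl hydroxylase of collagen (26.5-fold), Prss35 (26.3-fold), Tmem45a (24.4-fold), Kdelr3, a retrieval receptor of the endoplasmic reticulum (24.3-fold), and Lrrc15 (22.8-fold). Tnn (tenascin N) was 22.4-fold lower, and the sodium channel gene Scn7a was at least 18.6-fold lower. The 40 fibroblast and matrix genes with a log2 value of at least 10 in B-Gal negative cells were all above the floor in B-Gal positive cells, where Lum had a log2 value of 8.26 and Tnc 7.38. The 12 genes per direction were chosen on deposited values, and values under the floor have no order. With such values raised to the floor, 11 of the 12 higher genes would be chosen, and 9 of the 12 lower ones, without Cpa3, Mcpt4 and Scn7a.

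**Figure D2:**
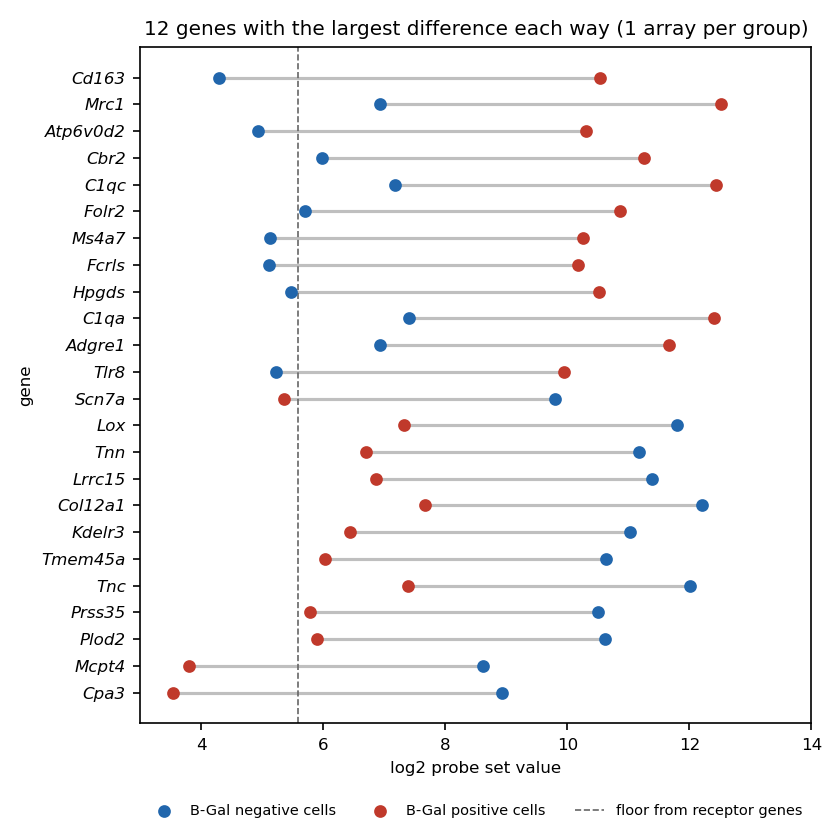
Log2 probe set values (horizontal axis) of the 12 genes with the largest difference of deposited values in each direction (vertical axis), in B-Gal negative cells (blue) and B-Gal positive cells (red), 1 array each; the dashed line marks the floor of 5.59. Cd163 stood at 4.29 in B-Gal negative and 10.54 in B-Gal positive cells, and Cpa3 at 8.93 and 3.54.

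Matrix proteases and their inhibitors had a median of -1.25 (percentile 0), 16 of 29 at least 2-fold lower and 6 higher. Without the 5 members that another list also holds, the median was -2.40. The lower ones included Adam12 (20.4-fold), Adamts12 (19.9-fold) and the stromelysin gene Mmp3 (15.6-fold). Smooth muscle and myofibroblast contractile genes were at least 2-fold lower for 10 of 15 members and higher for 0 (median -1.89, percentile 0). Acta2, the smooth muscle actin of myofibroblasts, was 13.9-fold lower, and Cald1, which encodes caldesmon, 17.4-fold lower. Pericyte markers had a median of -2.04 (percentile 0), with 9 of 12 at least 2-fold lower and 0 higher, among them Pdgfrb (19.6-fold) and Rgs5 (15.4-fold). Endothelial markers had a median of -1.17 (percentile 0), with 13 of 22 at least 2-fold lower and 1 higher. Tek, the receptor of angiopoietins, was 6.74-fold lower, Ramp2 5.38-fold lower and Pecam1 3.30-fold lower.

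Mast cell markers were at least 2-fold lower for 9 of 10 expressed members and higher for 0, with a median of -2.66 (percentile 0). With values under the floor raised to it, the median was -1.81. The mast cell carboxypeptidase gene Cpa3 was at least 10.2-fold lower, the chymase gene Mcpt4 at least 8.21-fold lower and the tryptase gene Tpsab1 8.30-fold lower. Hdc, the histamine-forming enzyme gene, was 8.85-fold lower. T and NK cell markers had a median of -0.50 (percentile 0.46), with 6 of 19 at least 2-fold lower and 2 higher. Cd3g, a chain of the T cell receptor complex, was at least 3.42-fold lower, and Il2rb at least 4.36-fold lower. With the filter at the median of all genes this median was -0.98. Among neutrophil markers, 6 of 14 were at least 2-fold lower and 1 higher. S100a9 was 10.6-fold lower, S100a8 6.54-fold lower, and the chemokine receptor gene Cxcr2 at least 4.71-fold lower. The neutrophil median was 0.27 (percentile 85.3) and the mean -0.79. With the floor at the 99th percentile of the receptor genes or the filter at the median of all genes, the median was -2.16. That median, the mean and the median without members that another list also holds (-0.55) stood apart on the lower side.

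Of 5 expressed B cell markers, 3 were at least 2-fold higher and 0 lower, with a median of 1.18 (percentile 99.97). The leading members were Blnk, a signalling adaptor (at least 19.4-fold), and Cd22 (at least 3.27-fold), both under the floor in B-Gal negative cells. Without the filter on low values this median was 0.22, which did not stand apart, and with the floor at the 99th percentile of receptor genes it was 1.97, which did. Of 20 erythroid and platelet genes, 11 had a probe set of their own and 7 were expressed. Their median was 0.51 (percentile 98.2), with 2 of the 7 at least 2-fold higher and 0 lower. These were the chemokine genes Pf4 (18.5-fold) and Ppbp (4.75-fold). With the floor at the 99th percentile of receptor genes the median was 1.39, and the mean was 1.14, and both stood apart. The list no longer stood apart under quantile normalization (0.44), the offset (0.32) or random lists without matching (0.51).

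TCF and beta-catenin target genes were at least 2-fold lower for 8 of 24 members and higher for 0, and their median of -0.58 stood apart (percentile 0.01). Values were lower for 16 members and higher for 8. Medians of members redrawn at random with replacement ran from -1.26 to 0.06 in their central 95%, a range that includes 0. In the same arrays the fibroblast median was -3.31 and the macrophage median 3.03. The matricellular gene Ccn4 was 11.8-fold lower, the secreted Wnt-binding protein gene Sfrp2 10.6-fold lower, and Twist1, a transcription factor of mesenchymal cells, 9.16-fold lower. Axin2, a negative regulator of Wnt signalling induced by it, was 2.03-fold lower, with log2 values of 6.88 and 5.86 in B-Gal negative and B-Gal positive cells. Members that another list also held numbered 4, and the median without them was -0.58. With the floor at the 99th percentile of receptor genes it was -0.91. Among Wnt pathway components, 11 of 40 were at least 2-fold lower and 1 higher, with a median of -0.24 (percentile 1.16) and a mean of -0.61. Medians of their redrawn members ran from -0.59 to 0.10 in the central 95%. The ligand gene Wnt5a (at least 9.14-fold) and the receptor genes Fzd2 (8.30-fold) and Fzd1 (7.99-fold) had the largest differences, followed by the ligand gene Wnt2 (-2.49 on the log2 scale). Ctnnb1, which encodes beta-catenin, was 1.27-fold lower. The TCF family gene Tcf7l1 was 2.98-fold lower, while Tcf7l2 and Lef1 had differences of -0.41 and -0.07.

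TGF-beta and BMP signalling genes had a median of -0.68 (percentile 0), with 13 of 33 at least 2-fold lower and 4 higher. Among the lower ones were the receptor gene Bmpr1a (at least 13.1-fold), the procollagen C-proteinase gene Bmp1 (17.3-fold), the co-receptor gene Tgfbr3 (13.1-fold) and the ligand gene Tgfb3 (10.3-fold). Notch and hedgehog signalling genes had a median of -0.49 (percentile 0.24), 7 of 20 at least 2-fold lower and 2 higher. Examples were the Notch target Hes1 (6.01-fold) and the hedgehog signal transducer Smo (5.35-fold). Mitosis genes were at least 2-fold lower for 17 of 26 members and higher for 0 (median -1.16, percentile 0). Prc1, a midzone spindle protein gene, was 4.19-fold lower and the cyclin gene Ccna2 3.16-fold lower. DNA replication genes had a median of -0.47 (percentile 0.14), with 5 of 28 at least 2-fold lower and 0 higher. Rrm1 and Rrm2, which encode ribonucleotide reductase subunits, were 2.46-fold and 2.43-fold lower. The mean of that list, -0.45, did not stand apart. Ribosomal protein genes had a median of -0.23 (percentile 0.82), and 0 of 25 differed by 2-fold. Neither their mean (-0.26) nor their median against unmatched random lists stood apart.

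**Figure D3:**
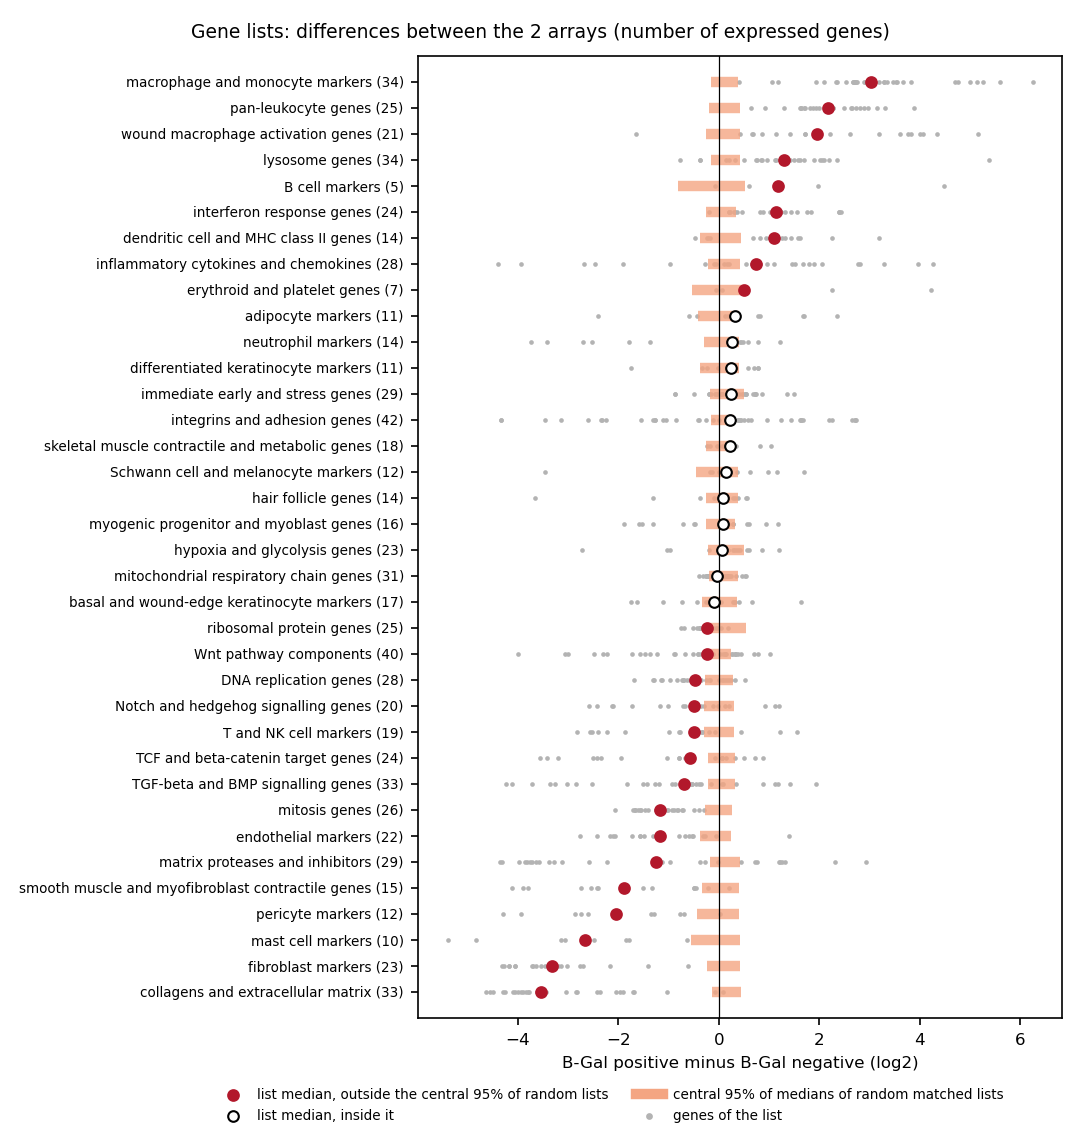
Differences between B-Gal positive and B-Gal negative cells (log2, horizontal axis) for 36 gene lists (vertical axis, number of expressed genes in parentheses); grey points are genes, bars the central 95% of medians of 10000 random lists matched on expression, and large points list medians, filled where they lie outside the bar. Medians run from -3.54 for collagens and matrix to 3.03 for macrophage markers, and 12 lists lie inside their bars.

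The remaining lists did not stand apart. Basal and wound-edge keratinocyte markers had a median of -0.09 (percentile 16.1). Of 17 members 3 were at least 2-fold lower, including Krt5 (at least 2.88-fold) and Krt14 (2.17-fold), and 1 was higher, the integrin gene Itga6 (3.10-fold). Differentiated keratinocyte markers had a median of 0.24 (percentile 81.5), with 1 of 11 at least 2-fold lower, Sbsn (3.34-fold). Hair follicle genes had a median of 0.09 (percentile 43.0) and a mean of -0.21, with 2 of 14 at least 2-fold lower, Cd34, also a fibroblast and endothelial gene (12.6-fold), and Sox9 (2.47-fold). Skeletal muscle genes had a median of 0.22 (percentile 88.8), and 0 of 18 were at least 2-fold lower. On deposited values 1 member, Myoz1, was over 2-fold higher (1.04 on the log2 scale), but its value in B-Gal negative cells lay under the floor, against which it was at least 1.56-fold higher. Myogenic progenitor genes had a median of 0.08 (percentile 48.9) and a mean of -0.24, with 4 of 16 at least 2-fold lower and 1 higher. The lower ones included Des, the desmin gene (2.99-fold), and Itga7 (2.49-fold). With the floor at the 99th percentile of receptor genes their median was -1.32, which stood apart. Pax7, the satellite cell transcription factor gene, had log2 values of 5.96 and 6.24 in B-Gal negative and B-Gal positive cells, close to the floor.

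Adipocyte markers had a median of 0.31 (percentile 92.3), with 3 of 11 at least 2-fold higher and 1 lower. The higher ones were the lipoprotein lipase gene Lpl (5.12-fold), the lipase gene Pnpla2 (3.25-fold) and Pparg (3.18-fold), genes that macrophages also express, and the lower one was the desaturase gene Scd1 (5.30-fold). Without Scd1 the median was 0.54, which stood apart. Schwann cell and melanocyte markers had a median of 0.13 (percentile 71.8), with 2 of 12 at least 2-fold higher, Mitf (3.22-fold) and Cnp (2.23-fold), and 1 lower, the adhesion molecule gene Ncam1 (-3.45 on the log2 scale). With the filter at the median of all genes it was 0.62, which stood apart. Integrins and adhesion genes had a median of 0.23 (percentile 91.6) and a mean of -0.12, with 12 of 42 at least 2-fold higher and 14 lower. Other lists also held 11 of the members, and without them the median was -0.12, as it was without macrophage and pan-leukocyte genes, and it did not stand apart. The lower members included the cadherin gene Cdh11 (20.1-fold) and the integrin gene Itga11 (8.76-fold). Hypoxia and glycolysis genes had a median of 0.07 (percentile 36.1), with 1 of 23 at least 2-fold higher, Pfkfb3 (2.30-fold), and 2 lower, Adm (6.58-fold) and P4ha1 (2.04-fold). Respiratory chain genes had a median of -0.03 (percentile 22.4), and 0 of 31 differed by 2-fold. Immediate early and stress genes had a median of 0.23 (percentile 74.8), with 2 of 29 at least 2-fold higher, Dusp2 (2.82-fold) and Hspa1a (2.55-fold), and 0 lower. The actin gene Actb differed by 0.20.

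These values compare 2 arrays, and whether another pair of arrays would differ in the same way was not measured. After loess scaling the medians of the hair follicle, myogenic and Schwann cell lists were -0.09, -0.06 and -0.0036.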

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

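All tests of explanations in this part were chosen after the results were seen. Probe sets outside the gene comparison also differed between the arrays. Among the 1143 probe sets listing several genes and above the floor, 208 were at least 2-fold higher in B-Gal positive cells and 74 were lower. Among the 2606 probe sets above the floor without a listed gene, 342 were higher and 121 lower. For comparison, 22.6% of the expressed genes differed at least 2-fold, 1368 higher and 1753 lower. The median difference was 0.14 over all probe sets and 0.28 over the receptor genes, both on the higher side. No explanation for the higher counts in these sets was tested.

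The median of the TCF target genes was lower in the cells labelled B-Gal positive, the group in which a TCF reporter would be active. Of the 24 members, 8 were at least 2-fold lower, and 8 had higher values. A first candidate explanation is that the mouse's own lysosomal beta-galactosidase marked macrophages as positive. Its gene Glb1 differed by 0.32 on the log2 scale, short of the 2-fold difference set as the bound for this explanation. The bound against it was a value under 0 by more than 0.37, the spread of the receptor genes. Lysosome genes had a median of 1.30, with 22 of 34 at least 2-fold higher and 0 lower. Enzyme activity was not measured, and Glb1 RNA need not follow it, so this explanation stays open. An exchange of the labels of both arrays cannot be told apart from the mix of cell types, and each group has 1 array. Fewer fibroblasts could also give the direction of the target list median of -0.58, though expression of the targets in fibroblasts alone was not measured. A biological difference, with TCF activity in wound macrophages that does not raise these targets, was not tested.

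Among 40 abundant fibroblast and matrix genes, with a log2 value of at least 10 in B-Gal negative cells, 38 were at least 2-fold lower, and differences ran from -4.64 to 0.09 (Thbs1, a gene macrophages also express, named after its value was seen). Their median was -3.67, or 7.86% of the B-Gal negative level, with quartiles of -4.07 and -3.18. Whether stromal cells or their RNA were present in the B-Gal positive array was not decided. All 40 genes were above the floor in it, but of all 966 expressed genes this abundant in B-Gal negative cells 0 were at or under the floor, so that is not particular to stromal genes. The 6 genes over 13 had a median 1.62 closer to 0 than the 26 genes from 11 to 13 (-2.40 against -4.02). Scanner saturation of the brightest genes would give such a gap. Expression of some of them in macrophages, named above for Thbs1, would give it too, and bright genes outside these lists were not checked. The gap therefore does not decide whether saturation played a part. Saturation of the genes over 13 would also leave the differences of the 26 genes from 11 to 13 without an account.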

How the results depend on the processing

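The alternatives that raised values under the floor or left out members shared between lists were added after the data were seen. No list that stood apart and no named gene with a 2-fold difference turned its direction under any alternative run. Recomputed for the 166 named genes, 1418 values moved by less than the spread of the receptor genes and 76 by more. The loess fit moved the median difference of all probe sets from 0.14 to -0.0012, and 39.6% of the genes called under it were higher. At 1.5-fold, 2585 genes were higher and 2765 lower (48.3% higher), and at 4-fold, 415 and 788 (34.5%), as the thresholds themselves require for the counts. With the floor at the 99th percentile of receptor genes, medians were 0.80 for adipocyte, -0.29 for differentiated keratinocyte, -0.36 for hair follicle, -1.32 for myogenic and -2.16 for neutrophil genes. With the filter at the median of all genes they were 1.25 for adipocyte, 0.62 for Schwann cell and melanocyte, -0.73 for basal keratinocyte, -0.36 for hair follicle, -1.32 for myogenic and -2.16 for neutrophil genes, as fewer low genes were tested. Without a filter the B cell median was 0.22. The offset gave -0.33 for T and NK cell, 0.32 for erythroid and platelet, -3.01 for fibroblast, -1.57 for mast cell and -0.89 for mitosis genes, as an offset shrinks differences of low values. Raising values to the floor gave -1.81 for mast cell markers. List means were -0.45 for DNA replication, -0.61 for Wnt components, -0.21 for hair follicle, -0.79 for neutrophil and -0.26 for ribosomal genes. Quantile normalization gave 0.44 for erythroid and platelet genes and loess 0.064 for skeletal muscle genes. Unmatched random lists ended the standing of the erythroid and platelet (0.51) and ribosomal (-0.23) medians. The adipocyte median was 0.54 without its largest member, and the neutrophil median -0.55 without shared members. Where no reason is given, the cause was not tested. No paired analysis was possible because the groups have 1 array each. Genes near the floor, as in the B cell, keratinocyte, hair follicle and muscle lists, limit what these medians can show.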

Other observations

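The gene groups in this part were chosen after the data were seen, except the tissue-resident macrophage and monocyte genes, whose lists and test were written before their values were seen. Of 10 expressed Toll-like receptor genes, 8 were at least 2-fold higher in B-Gal positive cells and 0 lower, with a median of 2.39. Tlr7, an endosomal receptor for single-stranded RNA, was at least 22.9-fold higher and Tlr2, a receptor for bacterial lipoproteins, 6.07-fold higher. Complement genes divided, with 6 of 14 at least 2-fold higher and 6 at least 2-fold lower. The higher ones were C1qa, C1qb (25.9-fold), C1qc, the anaphylatoxin receptor genes C3ar1 (4.14 on the log2 scale) and C5ar1 (7.47-fold higher), and the properdin gene Cfp (12.9-fold). The lower ones were the C1 protease genes C1s1 (19.1-fold) and C1ra (4.95-fold), their inhibitor gene Serping1 (13.8-fold), C2, Cfb and Masp1, while C4b was 1.95-fold lower. Collagen-modifying enzymes and chaperones were at least 2-fold lower for 15 of 19 genes and higher for 0, with a median of -3.20. Among the lower ones were Plod2, Fkbp14 (18.4-fold), Pcolce (17.2-fold) and the collagen chaperone gene Serpinh1 (-3.90 on the log2 scale). Plod1 and P4hb differed by -0.83 and -0.86. This group overlaps with genes reported above. Its members Plod2 and Kdelr3 were among the 12 lower genes with the largest differences. Serpinh1, P4ha1, P4ha3 and Pcolce are also members of the collagen and matrix list.

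Some ligand and receptor genes lay on opposite sides. The receptor gene Csf1r was 11.5-fold higher and its ligand gene Csf1 7.06-fold lower. Cxcr4 was 4.38-fold higher and Cxcl12 8.10-fold lower, and Il6ra 5.44-fold higher while Il6 was 3.74-fold lower. In the other direction, Osm was 3.45-fold higher and Osmr 15.3-fold lower, and Pdgfb was 2.21-fold higher and Pdgfrb 19.6-fold lower. Il10 and its receptor gene Il10ra (6.97-fold) were both higher, as were Gas6 (3.70-fold) and its receptor gene Mertk (8.45-fold). Both Kitl and Kit were lower (-0.82 and -1.78 on the log2 scale), both Tnf and Tnfrsf1b were higher (1.52 and 2.01), and Ccl2 differed by -0.06 where Ccr2 differed by 2.34. Il34, another ligand of the Csf1r product, differed by -1.13 and Tnfrsf1a by -0.06. Vegfa and Kdr differed by 0.85 and -1.56, Igf1 and Igf1r by 0.67 and -0.42, and Pdgfa and Pdgfra by 0.16 and -4.32. The 31 expressed ligand and receptor genes, paired after their values were seen, included 12 that were at least 2-fold higher and 10 lower.

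The 34 expressed macrophage and monocyte markers were higher by unequal amounts around a median of 3.03 on the log2 scale, from 0.40 for Marco, 1.07 for Clec4e, 1.18 for Ccr1 and 2.09 for Cd14 to 5.25 for C1qc and 6.24 for Cd163, whose B-Gal negative value lay under the floor. Marco, Clec4e, Ccr1 and Cd14 are named here outside the naming rule. A test of whether 1 kind of macrophage was present, on the range of such differences, was written after the values were seen and then dropped. Its filter on the B-Gal negative value removed genes with large differences, and without the filter the range passes its bound of 2, but probe sets differ in background and other cells express several of the lower genes. A hypothesis is that B-Gal positive cells may hold more tissue-resident and fewer monocyte-like macrophages. The median was 1.96 over 8 tissue-resident genes and 1.16 over 11 monocyte genes. The gap of 0.80 lies between the bounds of 0 and 1 set beforehand, so these arrays cannot decide the hypothesis. A gap past either bound would not have decided it alone, because other cell types may express members of these lists. Markers of other cells also differed between the arrays, with a fibroblast median of -3.31. Of the monocyte genes 6 were at least 2-fold higher, among them Fgr (3.42-fold), and 2 lower, Plac8 (2.99-fold) and Hp (2.69-fold), while 7 of the tissue-resident genes were at least 2-fold higher and 0 lower.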
